A study of Mus musculus with 9 samples.

How the data were processed

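RNA was profiled in 9 libraries of HEI-OC1 cells, an immortalised mouse line derived from the organ of Corti that the labels describe as a cochlear hair cell line. The cells had been transduced with an empty vector (EV, 3 libraries), with wild-type LMX1A (WT, 3 libraries) or with the frameshift form of LMX1A (c915dup, 3 libraries). LMX1A is a LIM-homeodomain transcription factor. Per the labels' protocols, RNA was taken with Trizol and 1 µg of total RNA went into each TruSeq RNA library. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

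The deposited values are FPKM (fragments per kilobase of transcript and per 1e6 fragments), made by the authors for 55451 genes. No header names the unit, which was inferred from the values: each library summed to between 339489 and 358766, which rules out a fixed total of 1e6, and value times transcript length moved in equal steps within a library. Per the submitters' processing notes, the reads went through CASAVA 1.8, Trimmomatic, FastQC, HISAT2, RSEM and edgeR on GRCm38, with no role or order given. The series' design text names BWA and TopHat with Cufflinks in their place, and the values do not settle which was used. The table also lists human LMX1A on a contig of its own, so that reads of the transduced gene were counted apart from mouse Lmx1a. Whether counting used the strand is not given in the sources used here. A second deposited table of 16512 genes held identical values in 148608 of 148608 cells and added nothing, and a deposited table of correlations between libraries was not used here. Every column was assigned: EV and WT columns carry the numbers 1, 2 and 3 of their titles, while the c915dup columns are numbered 1, 3 and 4 and could be tied to their group only. They are called c915dup replicates 1, 3 and 4 after those columns.

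Depth was estimated from the modal step of the FPKM values in genes with 1 transcript and came to between 13.2 and 16.4 (in units of 1e6 fragments) per library, an approximation that entered no test. Between 11582 and 11884 genes per library reached 1 FPKM. Within-group pairs of libraries had identical values in at most 0.042% of genes. The variance of their differences, from the median squared difference, was 1.87 to 7.18 times that of the estimated counting noise. It was 4.84 to 7.18 times in pairs with a library numbered 1 and 1.87 to 1.89 times in the other pairs. None was therefore a copy of another, and all 9 libraries were counted as separate samples. Neither value shows whether they came from separate cultures.

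Before the data were examined, the groups, the tests, the alternatives, the rule for named genes and 30 gene lists were fixed. The plan named edgeR's quasi-likelihood test for counts, which was not used because the files hold FPKM, and limma for that case. Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries were kept, which left 11933 genes. All 9 libraries entered 1 limma fit with 3 group means (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend and robust), with two-sided tests and Benjamini-Hochberg adjustment over all genes tested, and a gene passed at an adjusted p under 0.05. A log2 difference is on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Pandas 2.3.3 with numpy 2.4.6 under Python 3.11.15 read the tables, and matplotlib 3.10.9 drew the figures.

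The 30 lists held 794 members, of which 793 were in the table and 540 were tested. The 29 lists with at least 3 tested members were tested on log2(FPKM + 1), in place of the planned log2 CPM, with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. They cover immediate early, inflammatory and NF-kB, interferon, unfolded protein and integrated stress response, heat shock and proteasome, oxidative stress, p53, cell cycle, histone, ribosomal protein, mitochondrially encoded, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, extracellular matrix, mesenchymal, epithelial, BMP and TGF-beta, Wnt, Notch, otic, hair cell, supporting cell, deafness, neuronal, midbrain dopaminergic, melanocyte, Schwann cell, immune and endothelial genes. Tested members shared between lists were Egr2 (immediate early and Schwann cell), Met (deafness and melanocyte) and Slc7a11 (stress response and oxidative stress).

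The rule for named genes took, per comparison, the 10 largest rises and the 10 largest falls among genes that passed, had at least 1 FPKM in the higher group, had no overlap between the libraries of the groups compared and had no predicted or clone name (between c915dup and WT 1 fall was eligible). It added LMX1A, up to 4 tested members per list with the smallest p, and the 5 rises and 5 falls shared by both comparisons with EV with the smallest larger p. Short RNA genes inside other genes, overlapping genes and genes with near-identical copies are uncertain, since the counting could split their reads. Some genes that the rule took are not reported here.

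Pairing by replicate number was checked from the deviations of libraries from their group means over all genes tested. EV and WT libraries of the same number had r = 0.62, 0.39 and 0.26, each above the set bound of 0.1 for pairing. Deviations cancel within a group, so a library numbered 1 that stands apart in each group also lifts the other numbers past that bound. The data therefore show number 1 apart from the rest but no pairing of the other numbers, and the labels state no pairing. Libraries numbered 1 also deviated together across groups (r = 0.62 to 0.66) and against the rest, and different numbers among the rest correlated at a like level (EV replicate 2 with WT replicate 3 had r = 0.275). Because the c915dup numbers cannot be matched beyond 1, the block compared number 1 with the other numbers, a coding chosen after the files had been seen, although a replicate block was planned. Blocked values are given beside the counts of genes and list members and the calls in the text that the block changes.

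On simulated data for WT against EV (200 changed genes, 5 draws, 11933 genes) the fit recovered 33.2%, 73.2% and 94.8% of genes changed by 1.3-fold, 1.5-fold and 2-fold and called 0.2 unchanged genes on average. The fit with the block recovered 70.0%, 93.2% and 98.2% and called 13.4 unchanged genes. The simulated libraries were drawn from the blocked fit, with the same effect of replicate number in each group and independent noise per gene. The draws therefore favour the block. They could not show false calls from a number effect that differs between groups or from correlation between genes. The list test found 1 of 1 shifted list and called 0 of the others, in a single draw with independent genes and no effect of replicate number. It could not show false calls that come from correlation between genes.

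Results were recomputed with a pseudocount of 0.1, no filter, both together, median-of-ratios scaling, LMX1A left out of the totals, only the 2 groups compared, a 2-fold bound, the replicate block, each library left out in turn, and for lists an estimated correlation and fry. After the files had been seen, 4 were added: libraries numbered 1 left out, the block with a correction for GC content and length, a filter at 5 FPKM, and a block by each number in EV and WT alone. Coordinates are those of the deposited table, on GRCm38.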

Results

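Transcript levels were measured by RNA sequencing in HEI-OC1 cells carrying an empty vector (EV), wild-type LMX1A (WT) or the frameshift form (c915dup), with 3 libraries in each group. The comparisons ask what each form of the transcription factor changes relative to the vector and how the frameshift form differs from the wild type. Depth was estimated at 13.2 to 16.4 (in units of 1e6 fragments) per library, and 11933 genes were tested with limma.

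The transduced gene followed the labels. Human LMX1A (ENSG00000162761, positions 3000 to 157848 of its own contig) was listed at 0 in all 3 EV libraries. It stood at 132 ± 0.87 FPKM in WT and at 156 ± 11.6 FPKM in c915dup (mean ± SD, n = 3), where the libraries held 170, 150 and 149 FPKM. The log2 difference between c915dup and WT was 0.24 ± 0.06 (SE) and did not pass (limma adjusted p = 0.175), whereas with the replicate block it did (adjusted p = 0.021). Without c915dup replicate 1 the difference was 0.18. Mouse Lmx1a was listed at 0 in every library.

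**Figure D1:**
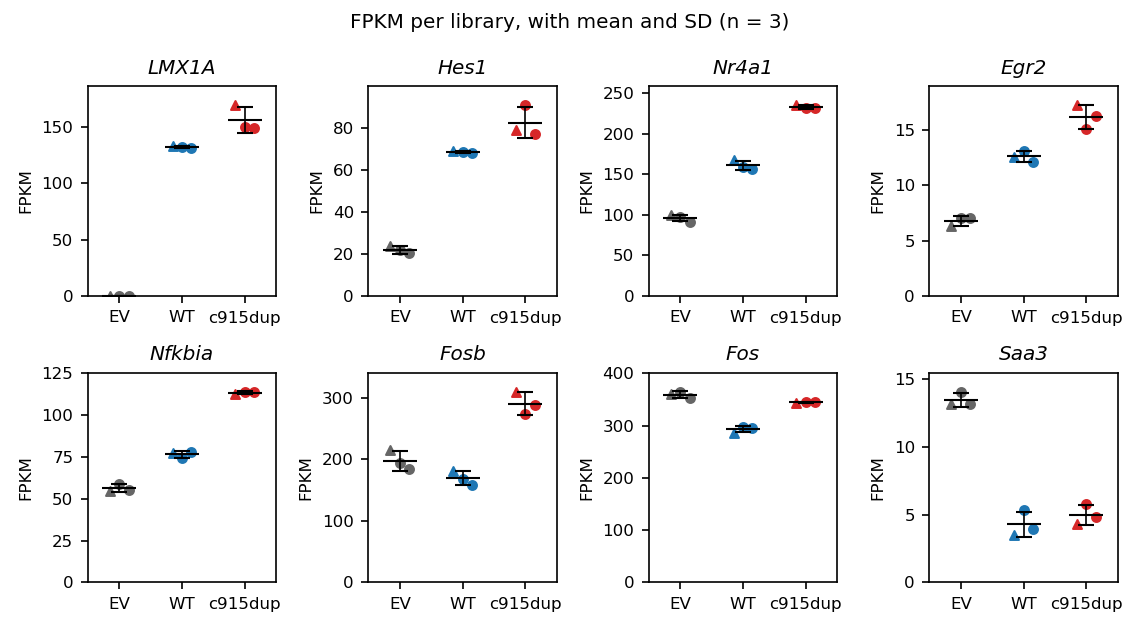
FPKM of 8 genes in each library of the EV, WT and c915dup groups, with horizontal bars for the mean and error bars for the SD (n = 3), and triangles for libraries numbered 1. LMX1A is listed at 0 in EV, Hes1 is near 21.9, 68.4 and 82.4 FPKM in the 3 groups, and Fosb is higher in c915dup (291 FPKM) than in WT (169 FPKM).

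Libraries split by replicate number before they split by group. Principal component 1, with 42.5% of the variance, set the 3 libraries numbered 1 apart from the other 6, and component 2, with 16.6%, ordered EV, WT and c915dup. Mitochondrial genes took 5.46%, 4.36% and 5.49% of FPKM in EV, WT and c915dup replicate 1, against 1.69% to 2.17% in the other libraries. The small RNA gene Gm23935 had 42.4 to 136 FPKM in libraries numbered 1 and 3684 to 6943 FPKM in the others. Each group held 1 such library. Log2 values correlated across genes at r = 0.989 to 0.994 within these classes and at 0.980 to 0.986 between them.

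**Figure D2:**
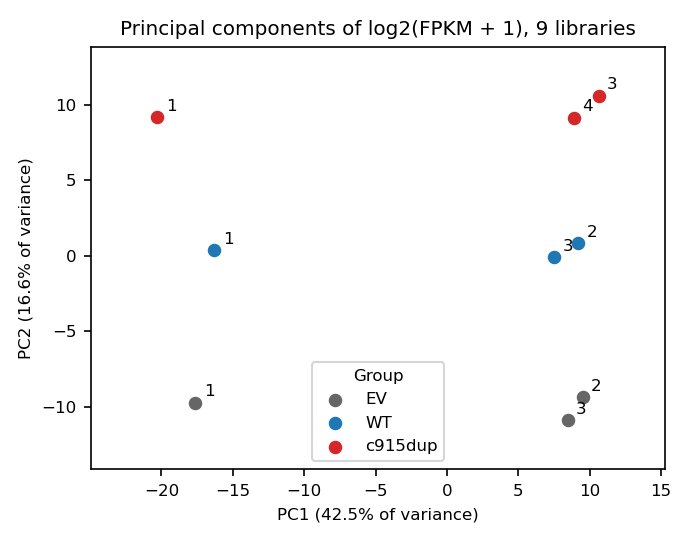
Principal components 1 and 2 of log2(FPKM + 1) over the genes tested, 1 point per library, coloured by group and marked with its replicate number. The 3 libraries numbered 1 lie apart from the other 6 libraries along component 1 (42.5% of the variance), and the groups lie in the order EV, WT, c915dup along component 2 (16.6%).

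In cells carrying WT, the transcriptional repressor Hes1 (chromosome 16, 30064384 to 30067796) showed the largest rise over EV among the genes that passed, the transduced LMX1A left out. It went from 21.9 ± 1.86 to 68.4 ± 0.56 FPKM (mean ± SD, n = 3), a log2 difference of 1.60 ± 0.08 (SE, limma adjusted p = 1.5e-05). Errfi1, a feedback inhibitor of EGF receptor signalling, rose from 24.3 ± 0.58 to 48.3 ± 3.15 FPKM (log2 0.96 ± 0.06, adjusted p = 0.00014). Genes known for fast induction by stimuli rose with them: Egr2 from 6.78 to 12.6 FPKM (0.81 ± 0.07), Arc from 9.0 to 16.1 (0.77 ± 0.06), Nr4a1 from 96.0 to 161 (0.74 ± 0.05) and the MAP kinase phosphatase Dusp5 from 7.98 to 15.1 (0.85 ± 0.09). The acute-phase gene Saa3 fell from 13.5 ± 0.52 to 4.28 ± 0.96 FPKM (log2 -1.47 ± 0.13, adjusted p = 0.00089), and the inducible nitric oxide synthase Nos2 (-0.81 ± 0.07), the lipocalin Lcn2 (-0.74 ± 0.08) and complement C3 (-0.49 ± 0.06) fell with it.

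Between WT and EV, 36 genes rose and 6 fell, LMX1A among the rises. Further large rises were the chemokine Cxcl1 from 84.4 to 144 FPKM (log2 0.77 ± 0.12), the small Maf factor Mafk from 9.60 to 16.9 (0.75 ± 0.06) and Ccn2 from 13.3 to 21.4 (0.65 ± 0.07). Mir6963 rose from 0.46 to 2.37 FPKM (log2 1.19 ± 0.17), but this short RNA gene (chromosome 15, 103350455 to 103350525) lies inside Itga5, and its value is uncertain. Fos fell from 359 ± 6.14 to 293 ± 5.93 FPKM (log2 -0.29 ± 0.04, adjusted p = 0.018). The neuronal growth-associated gene Stmn2 rose from 4.53 to 7.56 FPKM (0.63 ± 0.08) and the kinase gene Plk2 from 78.2 to 110 FPKM (0.49 ± 0.05).

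The immediate early genes had the smallest camera p of the lists: 5 of 22 measured members rose in WT, among them Nr4a1, Egr2, Dusp5 and Dusp6 (26.5 to 36.5 FPKM, log2 0.45 ± 0.06), 1 fell (Fos) and 16 did not pass. Adjusted over the list alone, 11 rose and 3 fell, and with the replicate block 9 rose and 3 fell. The camera adjusted p was 1.4e-10, and 0.0078 with an estimated correlation. Of the BMP and TGF-beta response genes, 3 of 18 rose, among them the secreted matricellular genes Ccn2 and Ccn1 (377 to 486 FPKM, log2 0.37 ± 0.04). Adjusted over the list alone, 4 rose and 2 fell, with the block 4 rose, and the camera adjusted p of 0.0066 became an adjusted p of 0.17 with an estimated correlation.

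Lists of other functions shifted upward in WT by camera with few members passing. Among interferon response genes 1 of 34 rose, the ubiquitin-like Isg15 from 100 to 131 FPKM (4 adjusted over the list alone, 3 with the block), with adjusted p = 4.8e-06 and an adjusted p of 0.19 with an estimated correlation. Of the unfolded protein and integrated stress response genes 0 of 28 passed (2 rose when adjusted over the list alone, 3 with the block), with asparagine synthetase Asns at 75.0 and 87.0 FPKM (log2 0.21, adjusted p = 0.12, 0.0086 with the block), adjusted p = 2.2e-05 and an adjusted p of 0.11 with an estimated correlation. The thrombospondin Thbs1 was the only 1 of 33 extracellular matrix genes to rise (0.33 ± 0.04; 2 rose when adjusted over the list alone and 4 with the block), with adjusted p = 0.0014 and an adjusted p of 0.26 with an estimated correlation. No cell cycle gene of 35 passed over all genes or adjusted over the list alone (Cdk1 had 28.1 and 32.0 FPKM), with adjusted p = 0.0022 and an adjusted p of 0.26 with an estimated correlation. Among mesenchymal and smooth muscle genes 1 of 20 rose, the myosin light chain Myl9 (0.52 ± 0.08; 3 adjusted over the list alone and 4 with the block), with adjusted p = 0.014 and an adjusted p of 0.26 with an estimated correlation. The 3 measured melanocyte genes did not pass over all genes (Gpnmb, at 42.4 and 51.1 FPKM, passed when adjusted over the list alone and with the block), with adjusted p = 0.0028 and an adjusted p of 0.24 with an estimated correlation. The list of 3 Schwann cell genes passed (adjusted p = 0.033, and an adjusted p of 0.26 with an estimated correlation) through Egr2, also an immediate early gene and its only member to rise, over all genes or adjusted over the list alone. With the block the list had adjusted p = 0.10. In the inflammatory and NF-kB list 3 of 22 rose and 3 fell (7 and 6 adjusted over the list alone, 4 and 4 with the block). Cxcl1 and the NF-kB inhibitor Nfkbia (56.1 to 76.4 FPKM, log2 0.44 ± 0.05) rose while Saa3, Lcn2 and C3 fell, and the list as a whole did not pass (adjusted p = 0.90). The other 19 lists did not pass either (adjusted p between 0.10 and 0.996). In the p53 list Plk2 alone passed, and with the block 1 rose and 2 fell. Of the mitochondrially encoded genes 1 was lower with the block. Median, mean and test differed in sign in the Wnt, otic, p53 and oxidative phosphorylation lists.

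With the replicate block 145 genes passed between WT and EV, 96 higher and 49 lower, including 41 of the 42, and 77.9% of these differences were under 0.5 in log2. The 3 values of WT and EV did not overlap in 12.9% of all genes tested, against 10% if the libraries were exchangeable. Libraries numbered 1 stand apart in each group, so they are not, and the share expected without a difference is not known. The blocked count was 78 without EV replicate 1, 87 without WT replicate 2 and 91 without EV replicate 3. Unblocked, the count was 19 without EV replicate 2 or EV replicate 3, 23 without WT replicate 2 and 27 without WT replicate 1. Calls such as those of Mir6963, Cxcl1, Fos, Stmn2, Isg15, Thbs1, Myl9 and Dusp6 were lost in at least 1 such fit (Fos in 8 of 9, the others in 4 or 5), whereas 15 of 24 calls of genes taken by the rule were kept in all 9.

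In cells carrying c915dup, Hes1 again showed the largest rise over EV with LMX1A left out, from 21.9 ± 1.86 to 82.4 ± 7.38 FPKM (mean ± SD, n = 3; log2 1.86 ± 0.08, limma adjusted p = 2.4e-06). The orphan nuclear receptors Nr4a2 (3.87 to 11.3 FPKM, 1.35 ± 0.13) and Nr4a1 (96.0 to 233, 1.27 ± 0.05) rose, as did the zinc finger factors Egr2 (6.78 to 16.2, 1.14 ± 0.07) and Egr3 (5.46 to 13.0, 1.12 ± 0.08). Cxcl1 rose from 84.4 ± 9.35 to 203 ± 30 FPKM (1.26 ± 0.12, adjusted p = 0.00061), Nfkbia from 56.1 to 113 FPKM (1.00 ± 0.05), Errfi1 to 54.6 FPKM (1.14 ± 0.06), Dusp5 to 19.8 FPKM (1.22 ± 0.09) and the salt-inducible kinase Sik1 from 15 to 32.7 FPKM (1.07 ± 0.07). Saa3 (-1.28 ± 0.13), Lcn2 (-0.96 ± 0.08), Nos2 (-0.64 ± 0.07) and C3 (-0.58 ± 0.06) fell.

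Between c915dup and EV, 115 genes rose and 15 fell. Further falls were the metalloreductase Steap4 from 14.7 to 9.46 FPKM (log2 -0.59 ± 0.06), the lipopolysaccharide-binding protein gene Lbp from 11.3 to 7.35 (-0.56 ± 0.07), the glycolytic regulator Pfkfb3 from 5.62 to 3.71 (-0.49 ± 0.07), Asb4 (-0.47 ± 0.08), Ccbe1 (-0.45 ± 0.09) and the receptor phosphatase Ptprf (-0.36 ± 0.07). Mir6963, inside Itga5, rose to 3.0 FPKM (1.46 ± 0.17), again with an uncertain value. Mafk rose to 20.5 FPKM (1.02 ± 0.06), Plk2 to 126 FPKM (0.68 ± 0.05), Stmn2 to 6.96 FPKM (0.53 ± 0.08) and the growth regulator Myc from 26.6 to 35.1 FPKM (0.38 ± 0.07). The platelet-derived growth factor receptor Pdgfra fell from 20.2 to 15.9 FPKM (-0.33 ± 0.05), while the contractile genes Acta2 (0.35 ± 0.06), Myl9 (0.45 ± 0.08) and Tagln (0.60 ± 0.12) rose.

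Immediate early genes rose in c915dup: 11 of 22 passed upward and 0 downward (18 and 0 adjusted over the list alone, 19 and 0 with the replicate block), with camera adjusted p = 2.1e-24 and 0.00072 with an estimated correlation. Cholesterol synthesis genes were lower as a list. The sterol demethylase Cyp51 fell from 79.6 to 64.3 FPKM (-0.30 ± 0.05), and the other 22 of 23 did not pass, whereas 1 rose and 12 fell when adjusted over the list alone and 1 rose and 14 fell with the block. The list had adjusted p = 1.5e-09 and an adjusted p of 0.067 with an estimated correlation. Of the glycolysis and hypoxia genes, the glucose transporter Slc2a1 (27.6 to 35.4 FPKM, 0.34 ± 0.06) and the angiogenic factor Vegfa (26.0 to 33.8, 0.37 ± 0.07) rose among 25. Adjusted over the list alone 7 rose, and 8 with the block, with adjusted p = 3.7e-07 and an adjusted p of 0.067 with an estimated correlation. Among BMP and TGF-beta response genes 6 of 18 rose, such as Ccn1 (0.59 ± 0.04), Ccn2 (0.70 ± 0.07) and the inhibitor of differentiation Id1 (37.5 to 62.1 FPKM, 0.71 ± 0.12). Adjusted over the list alone, 7 rose and 2 fell, and with the block 6 rose and 1 fell, with adjusted p = 0.00047 and an adjusted p of 0.067 with an estimated correlation. The extracellular matrix list passed downward although its only member past the threshold, Thbs1, rose (0.33 ± 0.04), and 2 rose and 3 fell when adjusted over the list alone. The collagen Col12a1 stood at 35.9 and 28.1 FPKM (log2 -0.34, adjusted p = 0.058, 0.0011 with the block), and with the block 2 rose and 8 fell. The list had adjusted p = 0.0012 and an adjusted p of 0.39 with an estimated correlation.

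Several lists did not pass in c915dup against EV although members did. The inflammatory and NF-kB list had 6 rises and 3 falls among 22 (7 and 6 adjusted over the list alone, 7 and 7 with the block) and a median of -0.05 beside a mean of 0.09 (adjusted p = 0.81). Of the interferon response genes, the chemokine Cxcl10 (0.37 ± 0.06) and the antiviral Rsad2 (0.50 ± 0.08) rose (5 up and 1 down with the block), and the list had adjusted p = 0.51. Trib3 (0.38 ± 0.07), a pseudokinase gene of the stress response, was the only 1 of 28 in its list to rise (3 up and 1 down with the block, adjusted p = 0.35 for the list). With the block, members passed as follows in further lists: p53 5 up and 1 down (Plk2 alone without it), mesenchymal 3 up and 2 down (3 and 1 without it), cell cycle 3 up and 1 down, deafness 2 down and melanocyte 1 up (0 without it in these 3). The 13 mitochondrially encoded genes (adjusted p = 0.87) and the 38 ribosomal protein genes (0.24) passed upward with the block alone (adjusted p = 0.016 and 0.014), with 0 and 1 member called. Each had an adjusted p of 0.80 with the block and an estimated correlation. The other 19 lists did not pass either (adjusted p between 0.15 and 0.97). Median, mean and test also differed in sign in the interferon, supporting cell and oxidative phosphorylation lists.

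With the replicate block 661 genes passed between c915dup and EV, 410 higher and 251 lower, including all 130, and 84.1% of these differences were under 0.5 in log2. The values did not overlap in 16.9% of genes, against 10% for exchangeable libraries, which these are not because of libraries numbered 1. The blocked count was 320, 383 and 356 without EV replicates 1, 2 and 3, and 352 and 358 without c915dup replicates 3 and 4. Unblocked, the count was 61 without EV replicate 3, 63 without c915dup replicate 4, 67 without EV replicate 2, 70 without c915dup replicate 3 and 83 without EV replicate 1 or WT replicate 3. Of 41 named calls 17 (Pfkfb3, Asb4, Ccbe1, Ptprf, Stmn2, Myc, Id1, Trib3, Cxcl10, Rsad2, Cyp51, Slc2a1, Vegfa, Acta2, Pdgfra, Myl9 and Tagln) were lost in at least 1 fit of this kind. Those of Ccbe1, Ptprf, Trib3, Vegfa and Tagln were lost in all 9 and that of Slc2a1 in 8.

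Set directly against WT, cells carrying c915dup had more Fosb, a subunit of the AP-1 transcription factor: it rose from 169 ± 11.0 to 291 ± 18.4 FPKM (mean ± SD, n = 3), a log2 difference of 0.78 ± 0.08 (SE, limma adjusted p = 0.0031). Nr4a1 rose from 161 ± 5.91 to 233 ± 2.31 FPKM (0.53 ± 0.05), Egr3 from 8.21 to 13.0 (0.61 ± 0.08), Nfkbia from 76.4 ± 1.92 to 113 ± 0.77 (0.56 ± 0.05) and the circadian regulator Per1 from 9.33 to 14.8 (0.61 ± 0.08). The neuronal enolase Eno2 rose from 48.7 to 72.7 FPKM (0.57 ± 0.05), Rsrp1 from 49.8 to 73.0 (0.55 ± 0.06) and the cytokine Clcf1 from 12.1 to 17.9 (0.53 ± 0.05). The natriuretic peptide clearance receptor Npr3 was the only gene to fall, from 16.5 ± 0.15 to 11.2 ± 0.17 FPKM (-0.52 ± 0.05, adjusted p = 0.0031). Mir6994 (chromosome 19, 11923728 to 11923800, inside Patl1) rose from 0.056 to 1.57 FPKM (1.28 ± 0.20) and Snord34 (inside Rpl13a) from 5.03 to 8.11 FPKM (0.60 ± 0.08), both short RNA genes with uncertain values.

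Between c915dup and WT, 26 genes rose and 1 fell. All 22 immediate early genes had a mean difference above 0: 3 rose (Fosb, Egr3 and Nr4a1), 10 rose when adjusted over the list alone and 16 with the replicate block. Egr1 stood at 198 and 257 FPKM (log2 0.38, adjusted p = 0.062, 6.9e-05 with the block). The camera adjusted p was 8.1e-16, and 0.0025 with an estimated correlation. Hes1 stood at 68.4 and 82.4 FPKM (0.26 ± 0.08) and did not pass (adjusted p = 0.24), nor with the block (0.056).

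Extracellular matrix genes were lower in c915dup than in WT as a list. None of 33 passed over all genes, and 1 rose and 11 fell when adjusted over the list alone. Examples were fibrillin Fbn1 at 45.3 and 35.0 FPKM (log2 -0.36), thrombospondin Thbs2 at 94.7 and 78.5 (-0.27), and collagens Col3a1 at 410 and 338 (-0.28) and Col12a1 at 35.4 and 28.1 (-0.32), each with an adjusted p of at least 0.060, and of at most 0.0028 with the block. With the block 1 rose and 14 fell, and the list had adjusted p = 6.2e-11 and an adjusted p of 0.058 with an estimated correlation. Cholesterol synthesis genes were also lower: 0 of 23 passed, 7 fell when adjusted over the list alone and with the block, with Hmgcs1 at 232 and 195 FPKM (-0.25, adjusted p with the block 0.0042) and Cyp51 at 77.5 and 64.3 (-0.26, 0.0022). Their adjusted p was 4.7e-09, with an adjusted p of 0.082 with an estimated correlation. Glycolysis and hypoxia genes were higher: 0 of 25 passed, 10 rose when adjusted over the list alone and with the block, with Slc2a1 at 27.9 and 35.4 FPKM (0.33, adjusted p with the block 0.0028), Vegfa at 26.4 and 33.8 (0.34, 0.0034) and the isomerase Gpi1 at 127 and 145 (0.19, 0.023). Their adjusted p was 2.3e-09, with an adjusted p of 0.058 with an estimated correlation.

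No member passed over all genes in the 5 other lists called between c915dup and WT. Deafness genes were lower (tenascin Tnc at 19.0 and 15.4 FPKM, adjusted p with the block 0.0075, 3 fell when adjusted over the list alone and with the block), with adjusted p = 0.0021 and an adjusted p of 0.36 with an estimated correlation. Interferon response genes were lower (Ifit1 at 33.5 and 28.5 FPKM, adjusted p with the block 0.013, 1 fell when adjusted over the list alone and 4 with the block), with adjusted p = 0.0042 and an adjusted p of 0.36 with an estimated correlation. Unfolded protein and stress response genes were lower (Pdia4 at 176 and 158 FPKM, adjusted p with the block 0.021, 0 when adjusted over the list alone, 1 up and 2 down with the block), with adjusted p = 0.031 and an adjusted p of 0.35 with an estimated correlation. Ribosomal protein genes were higher (0 when adjusted over the list alone, 8 with the block), with adjusted p = 0.015 and an adjusted p of 0.36 with an estimated correlation. BMP and TGF-beta response genes were higher (Id2 at 40.8 and 55.8 FPKM, adjusted p with the block 0.031, 5 rose when adjusted over the list alone and 3 with the block), with adjusted p = 0.017 and an adjusted p of 0.16 with an estimated correlation. The inflammatory and NF-kB (adjusted p = 0.10), p53 (0.15) and mitochondrially encoded (0.68) lists passed upward, and the mesenchymal list (0.15) downward, with the block alone (adjusted p = 0.035, 0.046, 0.00028 and 0.045). With the block and an estimated correlation the adjusted p was 0.39, 0.24, 0.42 and 0.46. Without the block Nfkbia alone passed in these 4 lists, and with it the NF-kB list had 4 up and 1 down, p53 5 up, mitochondrially encoded 2 up and mesenchymal 2 down. Among uncalled lists the cell cycle list had 2 up and 1 down and the Schwann cell list 1 up with the block alone. The other 16 lists did not pass (adjusted p between 0.11 and 0.85). Median, mean and test differed in sign in the heat shock, epithelial, Notch, dopaminergic and immune cell lists. In each of the 3 comparisons the immediate early list was the only 1 to hold with an estimated correlation.

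With the replicate block 574 genes passed between c915dup and WT, 374 higher and 200 lower, including all 27, and under median-of-ratios scaling 62 passed, 49 higher and 13 lower. Of the blocked differences 89.7% were under 0.5 in log2. Values did not overlap in 16.1% of genes, against 10% for exchangeable libraries, which these are not because of libraries numbered 1. The blocked count was 371, 226 and 235 without WT replicates 1, 2 and 3, and 328, 198 and 196 without c915dup replicates 1, 3 and 4. Unblocked, the count was 8 without WT replicate 3 or c915dup replicate 3, 10 without EV replicate 3 or WT replicate 2, 12 without WT replicate 1 or c915dup replicate 4 and 13 without EV replicate 2 or c915dup replicate 1. Of the 11 named calls those of Mir6994, Per1, Egr3, Snord34 and Rsrp1 were lost in at least 1 of these fits (Mir6994, Egr3 and Snord34 in 7 of 9).

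Many of the same genes differed from EV in cells carrying either form of LMX1A. Apart from LMX1A, 41 genes passed in WT, and 37 of these passed the same way in c915dup, 33 higher and 4 lower. Hes1, Errfi1, Nr4a1, Arc (17.4 FPKM in c915dup, log2 0.88 ± 0.06) and Mafk were the 5 shared rises with the smallest larger p, and Saa3, Nos2, Lcn2 and C3 were the 4 shared falls. Of the 41, 33 had the larger difference in c915dup, 8 of them with a passing c915dup against WT test, and 0 had a passing test for a smaller difference. Simulated unchanged groups against a common simulated EV group shared 0 genes, and independent lists would share 0.33 higher and 0.0075 lower. The simulation drew every library anew, EV included, with independent noise per gene, so it holds no peculiarity of the real EV libraries. Across genes, which are not independent replicates, the differences correlated at r = 0.53 against 0.50 simulated, and their covariance exceeded the simulated covariance by 0.0078. The 3 EV libraries cannot be split into groups of at least 2, so part of the excess may come from the shared controls. With the replicate block 100 genes were shared, 77 higher and 23 lower (simulated mean 0.02), of 144 called in WT. Of those 144, 72 had the larger difference in c915dup, with 28 tests of a larger and 30 of a smaller difference passing against WT. The block leaves the log2 differences unchanged, so these tallies differ by the genes they count. Without EV replicate 2 or EV replicate 3 the shared count was 18, without WT replicate 2 it was 21 and without WT replicate 1 it was 22.

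**Figure D3:**
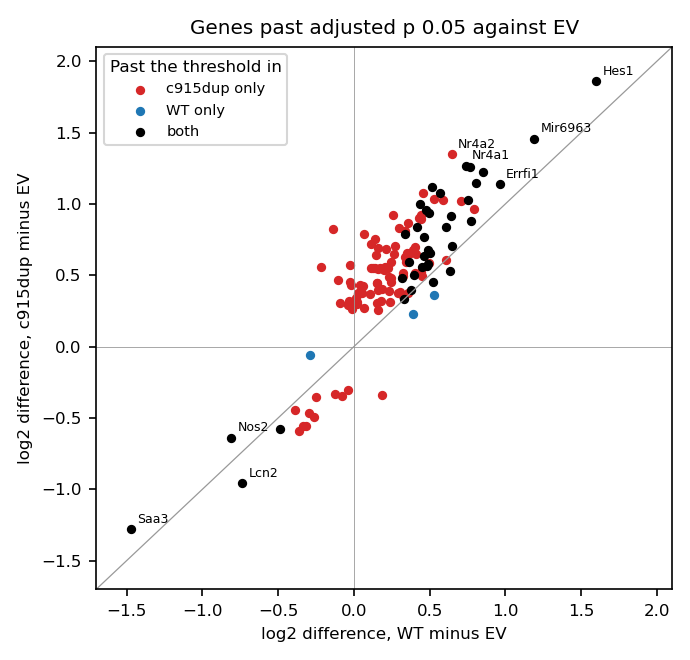
Log2 difference from EV in WT (horizontal) and in c915dup (vertical) of the 133 genes that passed in either comparison, 1 point per gene, coloured by where it passed; LMX1A, listed at 0 in EV, is left out. Differences have the same sign in 122 genes, 37 passed in both, and Hes1 lies at 1.60 and 1.86.

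Genes of the inner ear and of LMX1A's known developmental settings were mostly low in these cells. Of 37 hair cell genes 4 reached the level for testing, Myo6, Cib2, Whrn and Ikzf2, and 0 passed in any comparison over all genes. Whrn stood at 3.56 FPKM in EV and 4.71 in c915dup (log2 0.33, adjusted p = 0.15, 0.025 with the block). Of 25 otic genes 15 were tested and 0 passed (1, 2 and 1 lower with the block in WT against EV, c915dup against EV and c915dup against WT), with Bmp4 at 15.4, 12.6 and 12.4 FPKM in EV, WT and c915dup and an adjusted p with the block of 0.041 in WT and 0.013 in c915dup. Supporting cell genes (7 tested) had no member past the threshold without the block, and 1 higher and 1 lower in c915dup against EV with it. The neuronal list (7 tested) had Stmn2 alone. Nr4a2 was the only 1 of 5 tested midbrain dopaminergic and roof plate genes to rise, and it did so in c915dup. In WT it stood at 6.56 FPKM (0.65 ± 0.13, adjusted p = 0.14, 0.0010 with the block), and against WT it passed with the block alone (adjusted p = 0.072 and 0.00068). Among 10 Notch pathway genes Hes1 alone rose, and 1 was lower in c915dup against EV with the block, while Notch1 had 4.42, 5.20 and 5.14 FPKM. Of the 11 Wnt target genes Myc alone passed without the block, in c915dup against EV, and with the block it also passed in WT (adjusted p = 0.27 and 0.013), with 1 other lower in c915dup. Heat shock and proteasome (26 tested), histone (5), oxidative stress (26), oxidative phosphorylation (46), epithelial (3) and immune cell (5) genes had 0 members past the threshold in each comparison without the block, and none of these lists passed in any. With the block, oxidative phosphorylation had 1 lower in WT against EV, 1 higher and 1 lower in c915dup against EV and 3 higher and 2 lower in c915dup against WT. In the last 1 oxidative stress gene was lower and 1 histone gene higher, and 1 heat shock gene was higher in c915dup against EV. The endothelial list had fewer than 3 tested members and was not tested.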

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

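The comparison of effects was fixed by rule, whereas the tests of a handling stimulus and the weighing of libraries numbered 1 were chosen after the result was seen. Differences from EV had opposite signs in WT and c915dup, with a passing test between them, in 15 genes. The c915dup minus WT values in log2 were 1.28 for Mir6994, 0.78 for Fosb, 0.64 for Gm12940, 0.63 for Gm6093, 0.60 for Snord34, 0.57 for Eno2, 0.55 for Rsrp1, 0.52 for Gm49601, 0.45 for Srsf11, 0.40 for Anks3, 0.40 for Gigyf1, 0.35 for Dtx3, 0.33 for Med25, 0.32 for Rps13 and -0.52 for Npr3. Only Fosb (-0.22 in WT, 0.56 in c915dup) and Rsrp1 (-0.25 and 0.30) passed in both directions against EV with the replicate block, and none did without it. In the other 13 at least 1 of the differences from EV did not pass, with or without the block.

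Libraries numbered 1 stood apart in all 3 groups, and the reason is not given in the sources used here. A trend with GC content and length was excluded as the whole cause, because the smallest correlation between their deviations was 0.57 after the trend was taken out, from 0.62 before. Residual ribosomal RNA was weighed at 3 repeat loci alone. Their median log2 difference, other libraries minus number 1, was 0.183, which argues against these loci as the whole cause. The values were 0.144 at Gm42418, 0.545 at Gm26917 and 0.183 at Lars2, all higher in the other libraries, so a part for residual ribosomal RNA stays possible. Small RNA genes such as Gm23935, far higher in the other libraries, were not part of this test. Separate handling of that set of libraries could not be tested.

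Immediate early genes were higher with either form of LMX1A, more so with c915dup. Between libraries numbered 1 and the rest, the smaller list median (c915dup minus EV) was 0.521, so the difference was in both sets. Each group held 1 such library, so an effect shared by libraries numbered 1 cancels here, and the test could not weigh library number further. The trend with GC content and length was excluded, since taking it out left a median of 0.521. In WT 3 members were lower with the block (Fos at -0.29, Fosb at -0.22 and Jun at -0.29), and Fos alone without it. These values argue against a stimulus at handling that raises all members alike in WT. The test was set after they were seen, and it cannot weigh a stimulus with unequal effects on the members. In c915dup against EV 19 members were higher and 0 lower with the block, and 20 of 22 were above 0. Fos was not among these 20, at -0.06 (limma adjusted p = 0.66 without the block). The test counted called members alone, so for c915dup it left open a stimulus that raises all members alike. No biological reading is given, because handling of the cultures stays possible.

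Between c915dup and WT, matrix and cholesterol genes were lower and glycolysis genes higher. With the block and the GC and length trend taken out the list medians were -0.115, -0.142 and 0.15, so that trend was excluded. The medians kept their sign in libraries numbered 1 and in the rest in 3 of 3 lists, so the differences were in both sets. Each group held 1 such library, so an effect shared by libraries numbered 1 cancels here, and the test could not weigh library number further. Culture density or medium at harvest, which could move all 3 lists, was not tested, and none of the 3 calls held with an estimated correlation.

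Regrouping the 6 libraries of a comparison gives only 10 splits, or 6 with the block, too few for a share under 0.05. The real grouping alone reached its count in each gene comparison: 42 genes between WT and EV (highest other 1) and 145 with the block (1), 130 between c915dup and EV (1) and 661 with the block (0), and 27 between c915dup and WT (2) and 574 with the block (0). For lists the real counts of 9, 5 and 9 stood beside 3, 5 and 5 at most elsewhere, reached by 1, 2 and 1 of 10 splits. For the 37 shared genes 5 of 100 splits, the real 1 among them, were as large, with up to 1218 genes. That share was not under 0.05, the bound set beforehand, so without the block the test did not argue against a random grouping. The 4 others put all 3 libraries numbered 1 in the control place, whereas the real groups hold 1 each. This was seen after the test and does not change its result. Every other split shared at most 1 gene. With the block, and 1 such library per group, only the real 1 of 100 splits reached the 100 shared genes (highest other 85). That share is under 0.05, which argues against a random grouping of these libraries. The test does not separate the overlap from the effect of shared EV libraries, and the block coding was chosen after the files had been seen.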

How the results depend on the processing

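Counts are given in the order WT against EV, c915dup against EV, c915dup against WT and shared genes, from 42, 130, 27 and 37. The replicate block gave 145, 661, 574 and 100. No filter gave 24, 66, 10 and 21, and a pseudocount of 0.1 without a filter 76 in c915dup against EV and 9 against WT. Only the 2 groups compared gave 27, 63, 14 and 23, and at least a 2-fold change 5, 18 and 1. Median-of-ratios scaling gave 62 (49 higher, 13 lower) between c915dup and WT and 157 (123 higher, 34 lower) against EV. Of the alternatives added after the data were seen, leaving out libraries numbered 1 gave 85, 415, 361 and 59, the block with GC and length correction 166, 714, 586 and 106, and a block by each number in EV and WT alone 89. Leaving out each library in turn gave 19 (EV replicate 2) to 40 (c915dup replicate 1), 61 (EV replicate 3) to 111 (WT replicate 1), 8 (WT replicate 3) to 36 (EV replicate 1) and 18 (EV replicate 2) to 35 (c915dup replicate 1). Without c915dup replicate 1 the share higher in c915dup against EV was 76.2% in place of 88.5%. The LMX1A difference stayed 0.24 with the block, where it passed. Lists fell from 9, 5 and 9 to 1, 1 and 1 with an estimated correlation, while fry gave 9 in c915dup against EV and 5 in c915dup against WT. The block alone gave 8, 7 and 13 lists, and 8, 6 and 11 with GC and length correction, where 2 list calls were lost (Schwann cell, WT against EV, and ribosomal protein, c915dup against WT). Of 165 named gene results, each called with or without the block, 3 changed sign. None of these had passed without the block, and each had passed with it. For mt-Co1, WT against EV, the difference was 0.047 without EV replicate 1 and -0.652 without WT replicate 1. For mt-Co1, c915dup against WT, it was -0.054 without c915dup replicate 1 and 0.633 without WT replicate 1, and for mt-Nd1, c915dup against WT, -0.193 and 0.923. These omissions leave libraries numbered 1 unbalanced. Counts under the other planned settings stayed within 1.5-fold. Named gene calls lost numbered 5 (12 gained) with median-of-ratios scaling, 1 with a pseudocount of 0.1, 21 with that and no filter, 27 with no filter, 25 with only the 2 groups compared, and 4 (45 gained) without libraries numbered 1. TMM, library size alone, a CPM filter, DESeq2 and voom were not analysed here, since they need counts.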

Other observations

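Hes1 was higher in cells carrying either form of LMX1A, with 21.9 FPKM in EV, 68.4 in WT and 82.4 in c915dup, without a passing difference between the forms. Errfi1, Nr4a1, Arc and Mafk were higher in both, and Saa3, Nos2, Lcn2 and C3 lower in both. Whether LMX1A or a difference between the cultures is the cause was not tested. Of the calls, 37 of 41 genes called in WT were called the same way in c915dup, and 33 of the 41 had the larger difference there. Among the 144 genes called in WT with the block, 100 were called the same way, 72 were larger in c915dup, and 28 were called larger against 30 called smaller. A larger effect of c915dup was thus not general among these genes. They were chosen for passing in WT, which favours large WT differences. The transcript of the frameshift form stood at 156 FPKM against 132 for WT, and protein was not analysed here.

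Cells with c915dup differed from WT cells in Fosb, Nr4a1, Egr3, Nfkbia, Per1, Eno2 and Clcf1, all higher, and in Npr3, which was lower. When each library was left out in turn, the call of Egr3 was lost in 7 of 9 fits and that of Per1 in 3. The other calls named here were lost in 0. Hair cell genes were few at the tested level, and none of the 4 passed without the block (Whrn alone with it, adjusted p = 0.025 in c915dup against EV), so these data say little on hair cell identity.

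The genes and tests of this paragraph were chosen after the result was seen. Genes were taken as splicing factors by the start of their symbol alone, such as Srsf, Hnrnp, Rbm or Clk. The set therefore also holds genes like the pseudogene Rbm3-ps. Of its 109 genes 1 was higher in c915dup than in WT without the block, Srsf11 (log2 0.45 ± 0.07, adjusted p = 0.039). Of the other 108, 14 were higher and 2 lower with the block. With the block Clk1 stood at 30.2, 23.7 and 32.0 FPKM in EV, WT and c915dup (adjusted p = 0.047 and 0.010 for WT against EV and c915dup against WT). A hypothesis that RNA-processing factor genes are higher as a family was set against 108 members not already called, of which 65 were above 0 (median 0.03). The camera p was 0.0255 with the block, but 0.507 with an estimated correlation. Across genes the c915dup against WT difference followed log2 transcript length (r = -0.279), yet with the GC and length trend taken out the family stayed higher (median 0.05, camera p = 0.00169), so that trend does not account for it. With an estimated correlation p was then 0.332, so the hypothesis remained open.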
